A study of Mus musculus with 12 samples.

How the data were processed

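DMC1 single-stranded DNA sequencing (SSDS) was used in the testis of adult male mice. DMC1 is the meiotic recombinase that coats the single-stranded DNA on either side of a double-strand break, and SSDS recovers this DNA, so that each enriched interval is a place where recombination starts, called a hotspot. The series holds 12 samples. Of these, 2 are DMC1 samples of wild type B6 mice and 2 are DMC1 samples of Ankrd31 knockout mice. The labels give the knockout mice by their allele alone, so their genetic background is not given in the sources used here, and strain differences can enter any difference between the lists. The other samples, H3K4me3 chromatin immunoprecipitation and input DNA from mice of 13 days, were not analysed here.

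The analysis started from 2 deposited hotspot lists, 1 for each genotype. Whether the authors pooled the 2 animals of a genotype or joined separate calls is not given in the sources used here, so each list was treated as 1 sample, with no replicate check and no p-value between genotypes. The submitters' processing notes name CASAVA, Bowtie2, BWA and MACS2 and the mouse build mm10, without versions or the role of each tool. The names of the lists say that the Y chromosome was left out. The deposited read count of each hotspot is a whole number, per the file headers the reads of the signal. The deposited background signal is an estimate that falls on steps of 2.5 reads in 100% of hotspots of both lists, so it is a scaled value and not a count. The deposited strength is a signal value equal to the read count minus this background in 100% of hotspots. The deposited percent strength is the strength as a percent of the summed strength of the list, and the deposited rank orders the hotspots of a list by strength. No scaling between the lists was visible in the values, and whether libraries were reduced to a common depth is not given in the sources used here.

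The wild type list held 4376692 reads in hotspots and the knockout list 4203380 reads. Background made up 4.39% of the reads in wild type hotspots and 6.03% in knockout hotspots. The median hotspot had 163 reads in the wild type and 116 in the knockout, and the weakest listed hotspot had 28 and 23 reads. Total library depth was not used here. A sum over a list depends on how many intervals were called, so covered length and mean strength are given beside ratios of such sums.

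Hotspots of the lists were paired with bedtools 2.31.1 where they overlapped by at least 1 bp, and hotspots with no partner were called wild-type-only or knockout-only. These names refer to the lists: a hotspot just below the calling threshold of a list is missing from it. All 11487 overlapping pairs were 1 to 1, with a median overlap of 1539 bp. The overlap from chance was measured by placing the hotspots of a list at random within their chromosome, outside its first 3 Mb, 100 times with a fixed seed. Strengths of shared hotspots were compared as relative strength, the strength divided by the median strength of the autosomal shared hotspots of the same list (182 in the wild type and 151 in the knockout), and as log2 of knockout over wild type. Terms such as lower or weaker refer to relative strength unless values as deposited are named. A change of over 2-fold was used to count hotspots.

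Genes came from a RefSeq table of the mouse assembly GRCm38.p6, whose coordinates are those of mm10, with 49550 genes on the chromosomes used, 21627 of them protein-coding. The table gives no strand, so transcription start sites could not be told from gene 3′ ends. The planned test of promoters was therefore run on gene ends: a hotspot was at a gene end when its centre lay within 1 kb of either end of a protein-coding gene. This departs from the plan fixed in advance. Lengths of mm10 chromosomes, used for windows and random placement, were written by hand from general knowledge of the assembly and not copied from a file. Against them, 0 genes of the table and 0 hotspots ended beyond a chromosome, and the last gene or hotspot ended 101 to 353 kb before it did. Every distal-end value rests on these lengths. Start positions are given as the lists have them, and whether these count from 0 or 1 is not stated. The pseudoautosomal region was measured as X from 170 Mb on, and the distal end of an autosome as its last 1 Mb.

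The 4 gene lists of meiotic, ubiquitously expressed, spermatid, and Sertoli and Leydig cell genes and the family of olfactory receptor genes were fixed before the data were examined. The rule for naming hotspots was fixed then too, but most hotspots it names are picked by their values in these lists. The rule for naming took the 10 strongest knockout-only, the 10 strongest wild-type-only and the 10 strongest shared hotspots (by wild type strength). It also took the 5 shared hotspots with the largest relative increase and the 5 with the largest decrease among those in the stronger part of either list, every hotspot on X from 170 Mb on, and up to 8 members of each gene list with a knockout-only hotspot at an end, strongest first. A hotspot was named by the protein-coding gene whose end lay within 1 kb of its centre, else by the one that held it, else by the nearest one. Noncoding genes were not used for names. Some hotspots that the rule takes are not reported here. Other named items were chosen after their values were seen, and the text says so.

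Shares carry exact (Clopper-Pearson) 95% binomial intervals over hotspots, reads or genes. These cover counting error only, since reads are not independent molecules and 1 list per genotype says nothing of the spread between animals. Intervals of medians come from 1000 bootstrap resamples of chromosomes and describe the spread over the genome, with these exceptions. Single hotspots were resampled for shared hotspots at gene ends and elsewhere, on autosomes as on X, and for the neighbours on chromosome 8. For X against autosomes, X hotspots and whole autosomes were resampled. Neighbourhoods were resampled for other hotspots that gained strength. The closing tests of distal ends and the widths used fewer resamples of chromosomes. Intervals of single hotspots are binomial intervals of the 2 read counts before background subtraction. Each gene list was set against 10000 random lists of as many protein-coding genes, as a description of these lists. Correlations over the 19 autosomes have two-sided p-values from 100000 permutations, with Benjamini-Hochberg adjustment over 8 tests.

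The code of the pairing and of the gene-end step was checked on simulated data before use, with 5000 and 4000 simulated hotspots. Of planted pairs, 99.9% were recovered, a planted sharing of 60% was measured as 60.3%, and 100% of hotspots planted at gene ends were found there. Hotspots were planted well inside the distances asked, so this checks the code alone and says nothing about calling thresholds, depth or weak hotspots. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

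The alternatives tried were reciprocal overlap of 50%, centres within 500 bp, equal numbers of hotspots, the stronger part of each list, other scalings, autosomes only, mean in place of median strength, X with the 1 Mb before 170 Mb added, the last 3 Mb of autosomes, shares of hotspots in place of strength, windows of 500 bp and 2 kb around gene ends, and summed strength per Mb. After the data were seen, 4 alternatives were added: ends of all annotated genes, gene ends on autosomes only, distal ends within shared autosomal hotspots only, and shared hotspots without the part of chromosome 8 from 45 to 49 Mb. The planned analysis of hotspot sequence was not run because no genome sequence was used here, and the planned test over replicates was not run because the lists hold no column for a single animal.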

Results

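Recombination initiation in the testis of adult wild type B6 mice and of Ankrd31 knockout mice was compared from DMC1-SSDS hotspot lists. The series has 2 DMC1 samples per genotype and 1 list for each genotype, and which samples a list holds is not given in the sources used here. ANKRD31 is a protein of the machinery that forms meiotic double-strand breaks, and the series asks how its loss changes where and how often recombination starts, with an interest in the sex chromosomes. In B6 mice, most hotspots lie where the histone methyltransferase PRDM9 binds its DNA motif, away from promoters. The wild type list held 13480 hotspots with a mean width of 1783 ± 311 bp (SD over hotspots) and a median strength of 152 background-subtracted reads. The knockout list held 22034 hotspots of 1661 ± 331 bp with a median strength of 105. Expression of Ankrd31 is not measured by this assay. The gene lies on chromosome 13 from 96748289 to 96909794, where the wild type list had 1 hotspot and the knockout list 0. No difference between the genotypes could be set against a spread between animals, since the lists hold no replicate values.

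The first question was how many hotspots each genotype had and whether they were the same ones. The knockout list held 1.63 times as many hotspots as the wild type list. The ratio was 1.61 on the autosomes (20448 against 12663) and 1.94 on the X chromosome (1586 against 817). The number of hotspots called depends on library depth and calling threshold, which were not compared here. Of the wild type hotspots, 11487 (85.2%, 84.6 to 85.8) were also present in the knockout, against 2.98% after random placement. Of the knockout hotspots, only 52.1% (51.5 to 52.8) were shared, and the other 10547 were knockout-only. These knockout-only hotspots held 28.9% of the summed strength of the knockout list, while the 1993 wild-type-only hotspots held 4.02% of that of the wild type list.

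The ratio of hotspot numbers differed among autosomes. It was highest on chromosome 11 (1.96) and chromosome 19 (1.94) and lowest on chromosome 13 (1.19), chromosome 14 (1.23) and chromosome 15 (1.36). Chromosomes 13, 14 and 15 also had the most wild-type-only hotspots, with 160, 139 and 159. The knockout hotspots covered 36.6 Mb and the wild type hotspots 24.0 Mb, at a mean strength of 179 and 310 reads, so that the summed strength of the lists was alike (3949915 and 4184669). With the knockout list cut to its strongest hotspots, as many as the whole wild type list held, 65.7% of either list was shared.

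Hotspots found in a single genotype were the weaker ones of their list. Wild-type-only hotspots had a median strength of 65 against 185 for shared hotspots (log2 difference -1.51, interval over chromosomes -1.59 to -1.43). Knockout-only hotspots had a median of 76 against 156 for shared ones (-1.04, -1.09 to -0.97). In the wild type list, 99.6% of the strongest 20% of hotspots were shared and 59.5% of the weakest 20%. In the knockout list the same shares were 83.1% and 25.8%. Of the knockout-only hotspots, 1821 (17.3%) exceeded the wild type median strength of 152.

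The 10 strongest knockout-only hotspots all lay on the X chromosome. The strongest, X 45123400 to 45125268, had a strength of 3441, ranked 4 in the knockout list, and lay outside protein-coding genes, 31543 bp from Prr32. Next were hotspots at an end of Usp9x, which encodes a deubiquitinase (1474), inside Rap2c, a small GTPase gene (1241), inside Tsc22d3, which encodes a glucocorticoid-induced protein (1187), and at an end of Bclaf3 (1150). The others lay inside Vegfd (1123), at an end of Jade3 (1090), at an end of Taf7l, a germ cell paralogue of a TFIID subunit gene (1044), inside Rps6ka6 (1027) and at an end of Cfap47 (1005). The 10 strongest wild-type-only hotspots were weaker and spread over 9 chromosomes. They lay inside Stk3 on chromosome 15 (730), Scml1 on X (711), Ttc3 on chromosome 16 (628), Epc1 on chromosome 18 (625), Gnb1 on chromosome 4 (576), Kpna4 on chromosome 3 (528) and Tmtc1 on chromosome 6 (451), at an end of A430005L14Rik on chromosome 4 (543), and outside the nearest genes Usp12 on chromosome 5 (577) and Dock9 on chromosome 14 (542).

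Where the knockout-only hotspots lay was asked next, because breaks made without PRDM9 are known to fall on promoters. Many knockout-only hotspots sat on the end of a gene: 4919 of 10547 (46.6%, 45.7 to 47.6) had their centre within 1 kb of an end of a protein-coding gene, against 3.09% after random placement. The share was 36.3% to 55.4% on each single chromosome. Shared hotspots (344 of 11487, 2.99%, 2.69 to 3.32) and wild-type-only hotspots (61 of 1993, 3.06%, 2.35 to 3.91) were at gene ends about as often as random placement gave over all chromosomes (3.04% and 3.03%). On the autosomes their shares were 2.60% (2.31 to 2.92) and 2.73% (2.05 to 3.57), against 3.07% and 3.08% after random placement. On X they were 8.80% (6.85 to 11.1) and 10% (4.68 to 18.1), against 2.25% and 2.17%. The median distance to a gene end was 1879 bp for knockout-only and 41032 bp for shared hotspots, and 3500 knockout-only hotspots (33.2%) were centred within 250 bp of an end.

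**Figure D1:**
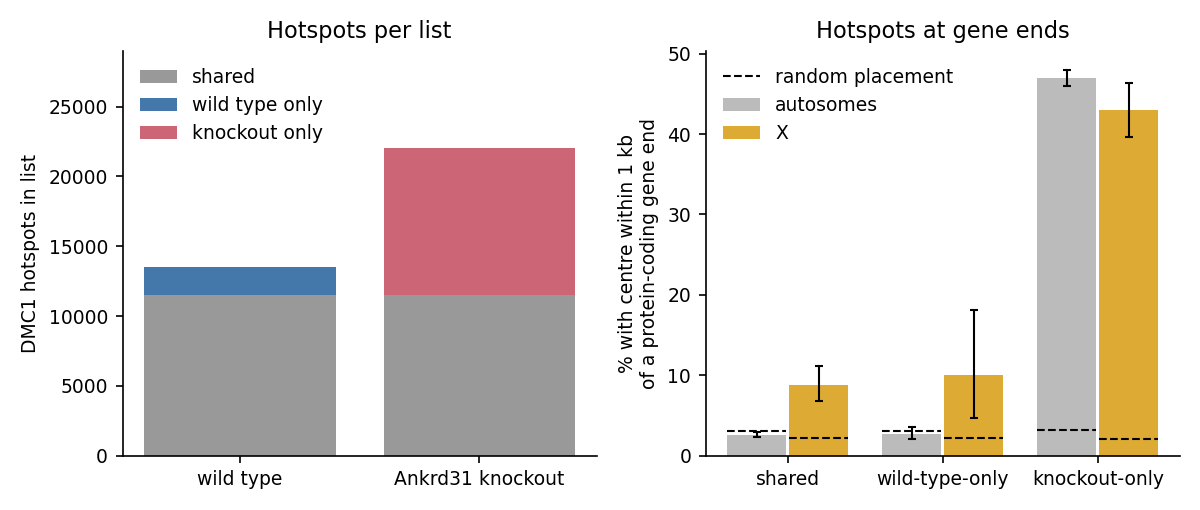
Number of DMC1 hotspots per list, split into shared and genotype-specific hotspots (left), and percent of each class with its centre within 1 kb of a protein-coding gene end on autosomes and X (right; bars are shares, error bars exact 95% binomial intervals, dashed lines random placement). Knockout-only hotspots reached 47% on autosomes and 43.0% on X, while shared and wild-type-only autosomal hotspots stayed near the share given by random placement.

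Of 21627 protein-coding genes, 5518 (25.5%) had a knockout-only hotspot at an end, while 431 (1.99%) had a hotspot of the wild type list there. Knockout-only hotspots at gene ends were stronger (median 94) than those elsewhere (median 66), and they held 16.2% of the summed strength of the knockout list. On the X chromosome, gene ends were already in use in the wild type, with 8.94% of hotspots (7.07 to 11.1) against 2.06% after random placement. On wild type autosomes the share was 2.62% against 3.08%. The wild type X hotspots at gene ends were weak (median strength 89, against 260.5 elsewhere on X). Wild type hotspots were stronger on X than on autosomes (mean strength 710 and 285). Autosomal gene ends in like use could therefore lie below the calling threshold, so the contrast does not show that only X used gene ends. The size of the shares at gene ends follows the window. Within 500 bp of a gene end they were 42.3% for knockout-only, 1.44% for shared and 1.30% for wild-type-only hotspots, and within 2 kb they were 50.3%, 5.61% and 6.97%. With the ends of all annotated genes, a window chosen after the data were seen, they were 53.9%, 6.29% and 5.92%.

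Gene lists fixed in advance differed in how often their members carried knockout-only hotspots. Among 42 ubiquitously expressed genes, 21 (50%, 34.2 to 65.8) had one at an end, more than in 99.93% of random lists of as many genes. These included Hprt, the purine salvage gene (strength 515), and Pgk1, a glycolysis gene (427), both on X. Others were the translation elongation factor gene Eef1a1 (348), Nono (301), the nuclear exportin gene Xpo1 (271), the chaperone gene Hsp90ab1 (258), the cyclophilin gene Ppia (215) and the helicase gene Ddx5 (213). Among 42 genes of meiotic recombination and synapsis, 18 (42.9%, 27.7 to 59.0) had one, more than in 99.05% of random lists. Members were Sycp3, which encodes an axial element protein (209), Gm960 (177), the crossover helicase gene Hfm1 (166), the meiotic cohesin gene Rad21l (157), Meioc (145), 4930447C04Rik (120), Mnd1, whose product assists DMC1 (120), and the crossover gene Msh5 (111).

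The other lists were not above random lists. Of 32 spermatid genes, 5 (15.6%, 5.28 to 32.8) had a knockout-only hotspot: Hook1 (238), Crisp2 (121), Odf2 (113), Clgn (97) and Spaca1 (58). That count was reached or undercut by 13.6% of random lists, and the interval includes the share of all protein-coding genes. Of 26 Sertoli and Leydig cell genes, 2 (7.69%, 0.946 to 25.1) had one, Dhh (134) and Hsd3b1 (50), and 2.33% of random lists had as few. Of 1110 olfactory receptor genes, 6 (0.541%, 0.199 to 1.17) had one, led by Olfr741 (123), Olfr122 (76) and Olfr155 (60), and 0% of random lists had as few. The first 4 lists had 0 genes with a wild type hotspot at an end, as had 42.75% to 59.88% of random lists of their sizes. A wild type hotspot lay at an end of 9 olfactory receptor genes (0.811%), and 0.15% of random lists had as few.

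**Figure D2:**
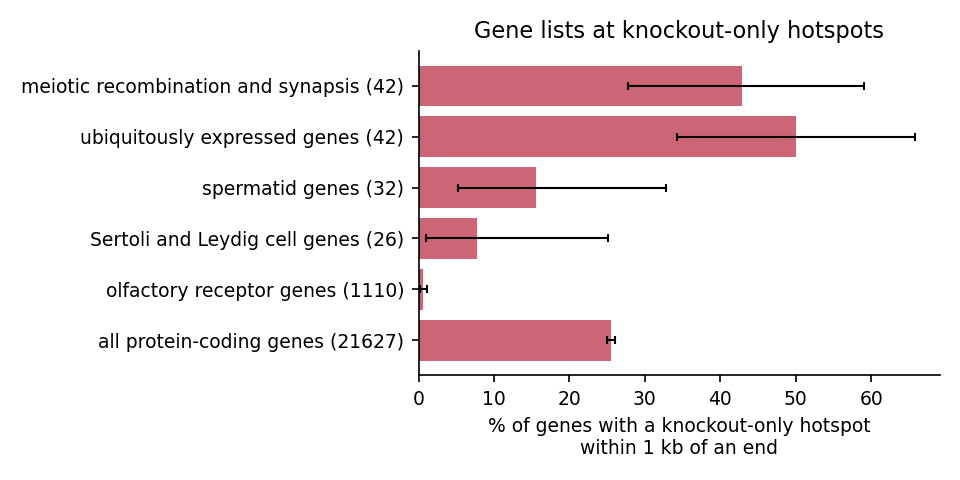
Percent of the genes of each list (number of genes in brackets) with a knockout-only hotspot within 1 kb of an end; bars are shares and error bars exact 95% binomial intervals. Ubiquitously expressed (50%) and meiotic genes (42.9%) lie above all protein-coding genes (25.5%), and olfactory receptor genes (0.541%) far below them.

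The shared hotspots show whether sites used in both genotypes kept their strength. Strengths were related across the 11487 shared hotspots (Spearman 0.72 over hotspots, which are not independent replicates), and single hotspots differed in both directions. Relative to the typical autosomal shared hotspot, 1816 (15.8%) were over 2-fold lower in the knockout and 1511 (13.2%) over 2-fold higher. The SD of the log2 ratio over hotspots was 0.97, and how much of it animals of 1 genotype would show was not measured. Weak wild type hotspots tended to be higher in the knockout and strong ones lower, with a median log2 ratio of 0.69 in the weakest 20% by wild type strength and -0.72 in the strongest 20%. Part of such a gradient arises whenever hotspots are ordered by one of the values compared.

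These counts depend on the scale. The median shared hotspot had a log2 ratio of -0.28 as deposited, and on these values 22.5% were over 2-fold lower and 7.78% over 2-fold higher. As shares of the summed strength of each list these were 20.5% and 9.15%, and among the stronger shared hotspots of the wild type alone 27.6% and 3.29%.

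The 10 strongest shared hotspots of the wild type all lay on X, and all were lower in the knockout, by 1.79-fold to 2.84-fold for those named here. A hotspot inside Stag2, which encodes a cohesin subunit, had a strength of 7177 in the wild type and 2184 in the knockout (log2 ratio -1.45, counting interval -1.52 to -1.38), and another inside Stag2 had 5395 and 1753. Others lay inside Rbm41 (6969 and 2036), Egfl6 (6841 and 2348), Phf6, mutated in a syndrome of intellectual disability (6794 and 2309), Glod5 (5149 and 2385) and Cask (4823 and 1658), and near Zmat1 (6066 and 2660) and 4930519F16Rik (4963 and 2140).

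Among the largest increases, 4 of 5 were on X and 4 of 5 at the end of a gene. The hotspot at an end of Tnfaip3 on chromosome 10, which encodes an inhibitor of NF-kB signalling, had a strength of 48 in the wild type and 1293 in the knockout, 32.5-fold higher in relative strength (log2 5.02, counting interval 4.39 to 5.18). On X, the hotspots at the ends of C1galt1c1 (47 to 1233) and Syap1 (58 to 1298) were 31.6-fold and 27.0-fold higher. One 29085 bp from Usp9x (40 to 1058) was 31.9-fold higher. The largest decreases were inside Ufsp2 on chromosome 8 (864 to 57, 12.6-fold lower) and Acsl1, an acyl-CoA synthetase gene on the same chromosome (969 to 81, 9.93-fold). Others lay outside Tnfrsf14 on chromosome 4 (753 to 51, 12.2-fold), Fgf10 on chromosome 13 (613 to 47, 10.8-fold) and Vmn2r87 on chromosome 10 (645 to 58, 9.23-fold). Most of the lower strengths in these pairs lay near the 5th percentile of their list (43 in the wild type, 40 in the knockout). The fold values are therefore imprecise.

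Gene ends on the X chromosome stood apart among shared hotspots. The 64 shared X hotspots at gene ends were weak in the wild type (median strength 92.5) and had a median log2 ratio of 3.22 (bootstrap interval 2.72 to 3.35), 9.31-fold higher in the knockout, and 50 of 64 were over 2-fold higher. The 663 shared X hotspots elsewhere had a median log2 ratio of 0.00 (-0.10 to 0.09). The 280 shared autosomal hotspots at gene ends had one of -0.22 (-0.37 to -0.09). Gene-end hotspots called in the knockout alone do not enter this comparison, and there were 4550 of them on autosomes and 369 on X. Shared autosomal hotspots lay at gene ends no more often than random placement gave (2.60% against 3.07%), unlike those on X (8.80% against 2.25%). The comparison therefore does not show that gains at gene ends were particular to X.

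**Figure D3:**
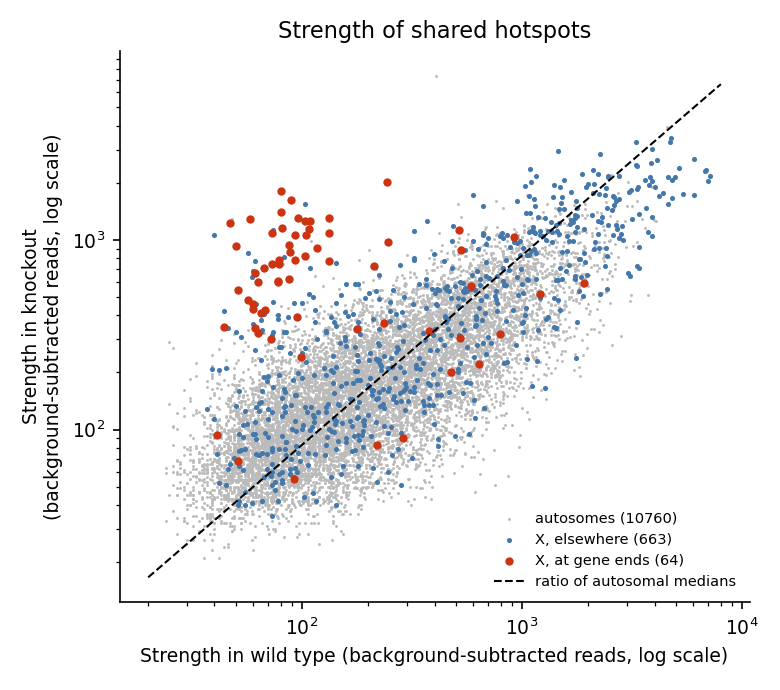
Strength of each shared hotspot in the wild type (x axis) and the knockout (y axis), both in background-subtracted reads on log scales, for autosomal hotspots, X hotspots at gene ends and X hotspots elsewhere; the dashed line is the ratio of the autosomal medians. Most of the 64 X hotspots at gene ends lie above the line, while the 10 strongest wild type hotspots lie below it.

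The X chromosome was compared with the autosomes as a whole, since in males its single unpaired copy keeps DMC1 longer. It held 6.06% of wild type hotspots (5.66 to 6.48) and 7.20% of knockout hotspots (6.86 to 7.55), and 13.9% (13.8 to 13.9) and 16.2% (16.2 to 16.2) of summed strength. X hotspots covered 1.56 Mb in the wild type and 2.92 Mb in the knockout, at a mean strength of 710 and 403. Of the 100 strongest hotspots, 61 in the wild type and 80 in the knockout lay on X. X hotspots exceeded autosomal ones within both lists, by a median log2 difference of 0.61 in the wild type (0.42 to 0.88) and 1.02 in the knockout (0.88 to 1.16). Which genotype had the larger excess depended on the measure: on mean strength both gave 1.32, and among the stronger hotspots of each list the differences were 0.84 and 0.75.

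The distal end of X, next to the pseudoautosomal region where X and Y recombine in males, was weaker in the knockout. In the 1 Mb before 170 Mb the wild type had 14 hotspots with 0.267% (0.262 to 0.272) of summed strength, and the knockout 12 hotspots with 0.0831% (0.0803 to 0.0860), a share 3.22 times lower, with covered lengths of 26.9 and 22.7 kb and mean strengths of 799 and 274. Of the 10 shared hotspots, 8 were lower, with a median log2 ratio of -1.67. In Mid1, the gene that spans the pseudoautosomal boundary, the 3 shared hotspots had log2 ratios of -2.20, -2.61 and -2.67, the last with 1269 in the wild type and 166 in the knockout. The strongest hotspot there, X 169463586 to 169465602, had 4609 and 1541. The hotspot at the end of Hccs, a mitochondrial enzyme gene, had a log2 ratio of 0.08 (-0.12 to 0.31), and one inside Arhgap6 had 1.03 (0.78 to 1.61). The hotspots of this stretch were named after their values were seen.

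Beyond the annotated end of Mid1, and so within the pseudoautosomal region, each list had 1 hotspot. That of the wild type lay at an end of Asmt, the last enzyme of melatonin synthesis, from 170672784 to 170674504 with a strength of 67 (0.0016% of summed strength). That of the knockout lay at X 169996930 to 169999076, 7205 bp beyond the end of Mid1, with a strength of 138. In the window fixed in advance, from 170 Mb on, this gave 1 wild type and 0 knockout hotspots, a count that follows from where the window starts. With so few weak hotspots no difference between the genotypes can be drawn from this region. How much of the region the mm10 assembly holds was not examined here. The 9 Mb of X up to the 1 Mb before 170 Mb held 0.850% of wild type strength (62 hotspots, 116 kb covered, mean strength 574) and 0.991% of knockout strength (105 hotspots, 187 kb, mean 373), and 28 of its 51 shared hotspots were lower in the knockout (median log2 ratio -0.13). From 150 to 160 Mb, 39 of 62 shared hotspots were lower (median -0.37), so a lower strength of shared hotspots was not limited to the 1 Mb before 170 Mb.

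**Figure D4:**
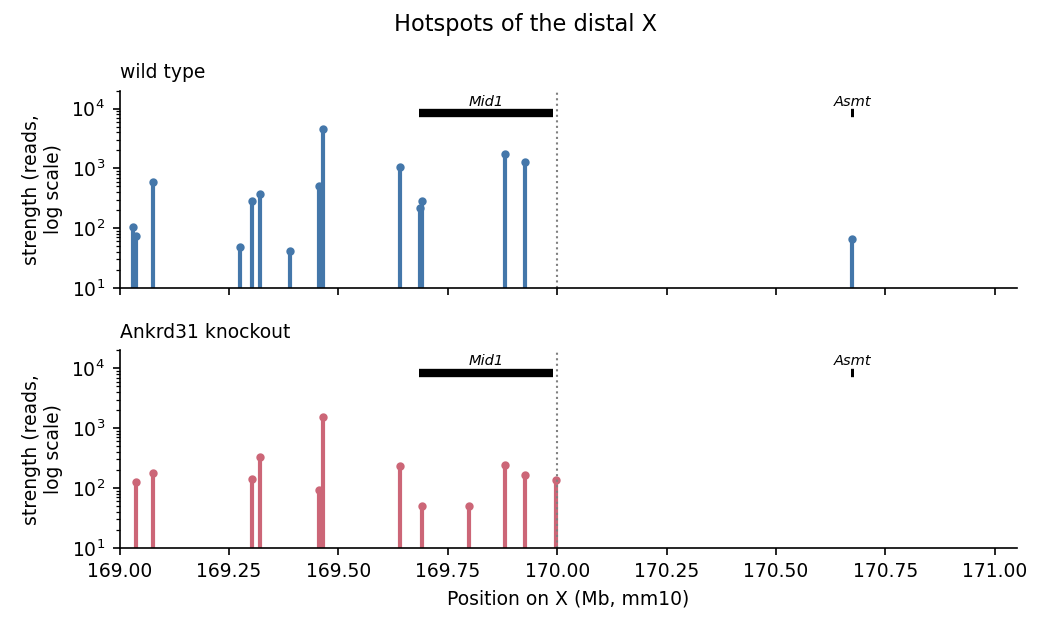
Hotspots of the distal X, from 1 Mb before the 170 Mb mark to its end, in the wild type (top) and the knockout (bottom), with position in Mb (mm10) on the x axis and strength in background-subtracted reads on a log scale; black bars are Mid1 and Asmt and the dotted line marks 170 Mb. The 3 shared hotspots inside Mid1 have lower stems in the knockout, and each list has 1 hotspot beyond the end of Mid1.

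Distal autosome ends were examined in the same way, with chromosomes 4, 9 and 13 set apart in advance because their ends are known to carry the mo-2 minisatellite also found in the pseudoautosomal region. The last 1 Mb of the 19 autosomes held much less hotspot strength in the knockout: 61 wild type hotspots held 0.299% (0.294 to 0.304) of summed strength and 24 knockout hotspots 0.0544% (0.0522 to 0.0568), a share 5.49 times lower. They covered 118 and 41.4 kb at mean strengths of 205 and 89.6. At the ends of chromosomes 4, 9 and 13 the wild type had 14 hotspots and the knockout 2, and the share was 16.9 times lower (0.0641% and 0.0038%), with 28.1 and 3.79 kb covered at mean strengths of 192 and 75. At the other 16 ends it was 4.64 times lower, with 89.9 and 37.6 kb covered at mean strengths of 209 and 90.9. Over the last 3 Mb the factor was 3.62 for all autosomes (473 and 245 kb, mean strengths 187 and 84.5). It was 9.39 for chromosomes 4, 9 and 13 (100 and 27.8 kb, 248 and 77.7) and 2.93 for the other 16 (373 and 217 kb, 170 and 85.4). The shared hotspots of the last 3 Mb had a median log2 ratio of -2.30 at chromosomes 4, 9 and 13 (13 of 13 lower) and -1.05 at the other 16 (83 of 97 lower). Those of the last 5 Mb had -1.64 and -0.88, but those of the last 1 Mb -0.84 (1 hotspot) and -1.51 (20 hotspots). Against the rest of their chromosome, the last 5 Mb differed by -1.95 on chromosome 13 (13 hotspots), -1.46 on chromosome 4 (6) and -1.37 on chromosome 9 (7). Chromosome 15 had -2.01 and chromosome 7 -1.36, so differences of this size were not limited to chromosomes 4, 9 and 13. Counting hotspots in place of strength, the last 1 Mb held 0.453% of the wild type and 0.109% of the knockout list. Within shared autosomal hotspots alone, an alternative chosen after the data were seen, the 21 hotspots of the last 1 Mb held 0.199% and 0.0826%, a factor of 2.41, and chromosomes 4, 9 and 13 had 1 such hotspot, with 0.0035% and 0.0024%.

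The lower strength extended inward over several Mb. Shared autosomal hotspots within 2 Mb of the distal end had a median log2 ratio of -1.18 (interval over chromosomes -1.72 to -0.93, 61 hotspots), those at 2 to 5 Mb -0.84 (-1.04 to -0.54, 190 hotspots) and those at 5 to 10 Mb -0.38 (-0.52 to -0.20, 467 hotspots). At 10 to 20 Mb it was -0.05 (-0.22 to 0.05), and at 20 to 40 Mb 0.13 (0.06 to 0.23). Hotspots of the last 5 Mb were lower than the rest of their chromosome on 19 of 19 autosomes, by a median log2 difference of -1.0, from -2.01 on chromosome 15 to -0.07 on chromosome 12. At the centromeric end, where positions were counted from 3 Mb on, shared hotspots of the first 2 Mb had a median of -0.44 (-0.62 to -0.16, below 0 on 11 of 18 autosomes), and those at 2 to 5 Mb one of -0.30 (-0.54 to -0.01), below 0 on 14 of 19 autosomes.

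**Figure D5:**
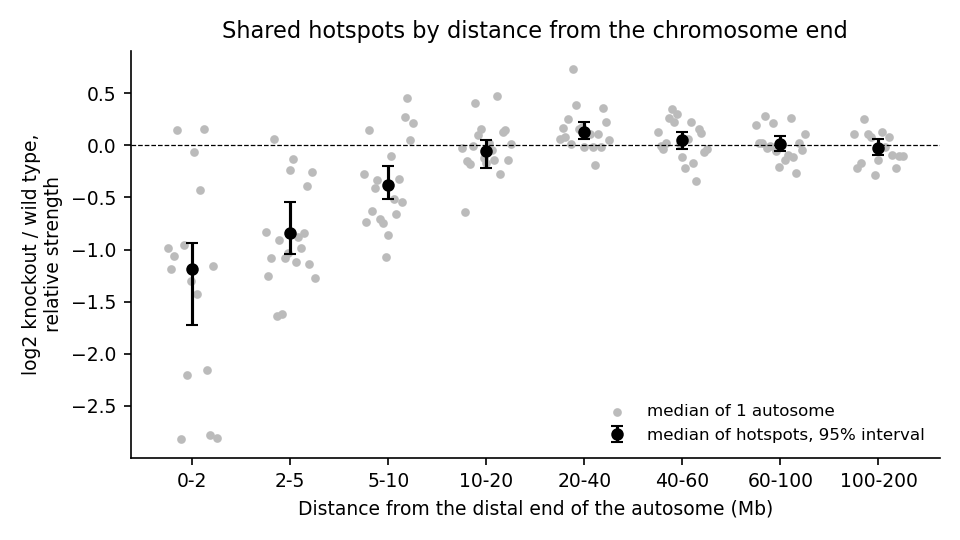
Median log2 ratio of knockout over wild type relative strength of shared autosomal hotspots by distance in Mb from the distal chromosome end; black points are medians over hotspots with 95% bootstrap intervals over chromosomes, and grey points are single autosomes. The median is -1.18 within 2 Mb of the end and returns to about the genome median at 10 to 20 Mb.

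Whether chromosome length set the density of hotspots was tested over the 19 autosomes. No relation of length with the knockout to wild type ratio of hotspot number was detected (Pearson r = -0.20, permutation p = 0.413, adjusted p = 0.413; Spearman -0.23, p = 0.333, adjusted p = 0.380). Without chromosomes 1 and 19, the farthest from the median length, r was 0.03. With summed strength in place of hotspot number, r was -0.45 (permutation p = 0.0493, Benjamini-Hochberg adjusted p = 0.140 over 10 tests; Spearman -0.39, p = 0.0979, adjusted p = 0.196), which does not pass the correction, and -0.23 without chromosomes 1 and 19. Knockout hotspots per Mb had a Spearman rho of -0.48 with length (permutation p = 0.0396, adjusted p = 0.149), which does not pass the correction. Their Pearson r was -0.32 (permutation p = 0.183, adjusted p = 0.293). For wild type hotspots per Mb, rho was -0.33 (permutation p = 0.174, adjusted p = 0.293) and r -0.24 (permutation p = 0.318, adjusted p = 0.380). Without chromosomes 1 and 19, r was -0.26 in the knockout and -0.38 in the wild type. Knockout-only hotspots per Mb were related to protein-coding genes per Mb only before correction (Pearson r = 0.49, permutation p = 0.0299, adjusted p = 0.149; Spearman 0.45, p = 0.0560, adjusted p = 0.149), and r was 0.36 without chromosomes 7 and 11, so it rests in part on these. The densities ran from 2.37 per Mb on chromosome 14 to 7.09 on chromosome 11.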

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

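Each of 24 results was recomputed under alternatives fixed before the data were examined, except 4 alternatives chosen after: ends of all annotated genes, gene ends on autosomes only, distal ends within shared hotspots, and shared hotspots without chromosome 8 from 45 to 49 Mb. Of 72 values, 31 stayed within the interval of the reported value and 41 moved beyond it; of the 13 that can take either sign, 0 changed it. Differences that follow from the setting itself are not repeated as causes, and for the others the cause was not tested. With equal numbers of hotspots, 65.7% of either list was shared. With the stronger hotspots of the asked list, 97.1% of the wild type and 69.9% of the knockout were shared. Shared hotspots over 2-fold lower and higher made up 22.5% and 7.78% with values as deposited, 20.5% and 9.15% as shares of summed strength, and 27.6% and 3.29% among the stronger hotspots of the wild type. The log2 excess of X over autosomes was 1.32 in the wild type and 1.32 in the knockout with mean strength, and 0.75 in the knockout with its stronger hotspots. With the 1 Mb before 170 Mb added, most of which lies outside the pseudoautosomal region, the share of strength was 0.269% in the wild type and 0.0831% in the knockout. From 170 Mb on, as a share of hotspots the wild type had 0.0074%, and 0% among its stronger hotspots. For the distal ends of 19 autosomes, wild type and knockout had 1.21% and 0.334% in the last 3 Mb, 0.453% and 0.109% as shares of hotspots, and 0.199% and 0.0826% within shared hotspots. For chromosomes 4, 9 and 13 these were 0.332% and 0.0354%, 0.104% and 0.0091%, and 0.0035% and 0.0024%, the last pair from 1 shared hotspot. The shares at gene ends for knockout-only, shared and wild-type-only hotspots were 42.3%, 1.44% and 1.30% within 500 bp, 50.3%, 5.61% and 6.97% within 2 kb, and 53.9%, 6.29% and 5.92% with all annotated genes. Among the stronger hotspots of a class, 58.5% of knockout-only and 3.96% of wild-type-only hotspots were at gene ends, and on autosomes 2.60% of shared ones. The ratio of hotspot numbers in the stronger part of each list is set by the lengths of the lists and tests nothing. Depth limits the weak end: the 5th percentile of strength was 43 reads in the wild type and 40 in the knockout, so absence of a weak hotspot from a list is not absence of breaks. No paired analysis was possible because the lists hold no column for a single animal; for the same reason no animal could be left out. The sequence of hotspots was not run.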

Other observations

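The gene families, noncoding genes, hotspot widths and gene counts by distance in the next 3 paragraphs were examined after the data were seen, as were the tests of extra copies and of loss of 1 or both copies on chromosome 8; the other tests were written down before their result was seen.

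Gene families, grouped by the start of their symbols, differed widely in how often their members carried a knockout-only hotspot at an end. Of 38 centrosomal Cep genes, 25 (65.8%, 48.6 to 80.4) had one, and so had 18 of 30 sorting nexin genes (60%, 40.6 to 77.3), 21 of 38 kinesin genes (55.3%, 38.3 to 71.4), 26 of 55 ubiquitin-specific protease genes (47.3%, 33.7 to 61.2) and 29 of 69 genes with Rab symbols (42.0%, 30.2 to 54.5). At the other extreme were 3 of 355 vomeronasal receptor genes (0.845%, 0.175 to 2.45), 1 of 53 keratin genes (1.89%, 0.0478 to 10.1), 1 of 42 beta-defensin genes (2.38%) and 0 of 40 secretoglobin genes (upper bound 8.81%). Ribosomal protein genes of the large subunit (13 of 53, 24.5%) were close to the share of all protein-coding genes (25.5%). Away from protein-coding ends, 25 of 300 tRNA genes (8.33%, 5.47 to 12.1) had a knockout-only hotspot and 5 (1.67%, 0.543 to 3.85) a wild type one. For long noncoding RNA genes the shares were 3.93% (3.54 to 4.36) and 2.47% (2.16 to 2.82), and for pseudogenes 2.24% and 1.20%. For snRNA genes they were 1.88% (1.08 to 3.04) and 0.824% (0.332 to 1.69), with overlapping intervals. The shares ran the other way, also with overlapping intervals, for snoRNA genes (0.470%, 0.153 to 1.09, and 1.03%, 0.517 to 1.84) and miRNA genes (0.618%, 0.201 to 1.44, and 0.989%, 0.428 to 1.94). Of all knockout-only hotspots, 5628 (53.4%) lay away from protein-coding ends, with a median strength of 66, and 13.5% of these were within 1 kb of the end of a noncoding gene.

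Knockout-only hotspots were rare near distal autosome ends in spite of the genes there. Of 480 protein-coding genes within 2 Mb of the end, 11 (2.29%, 1.15 to 4.06) had a knockout-only hotspot, against 91 of 607 (15%, 12.2 to 18.1) at 2 to 5 Mb, 277 of 897 (30.9%, 27.9 to 34.0) at 5 to 10 Mb and 3349 of 13465 (24.9%, 24.1 to 25.6) beyond 40 Mb, with 12.6 protein-coding genes per Mb in the last 2 Mb and 8.18 beyond 40 Mb. Across the autosomes, shared hotspots with many knockout-only hotspots within 500 kb were lower in the knockout, with a median log2 ratio of 0.23 for 0 such neighbours, 0.30 for 1, -0.10 for 5 and -0.60 for 10 or more. The ratio of background reads was -0.30 for 0, -0.44 for 1, -0.44 for 5 and -0.37 for 10 or more neighbours on the log2 scale, and ran from -0.51 for 9 to -0.29 for 8.

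Shared hotspots were narrower in the knockout at like strength. Among 1449 shared hotspots whose strengths in the lists were within 10% of each other, the mean width was 1765 bp in the wild type and 1595 bp in the knockout, and 81.4% were narrower in the knockout. The difference of -170 bp (interval over chromosomes -183 to -155) had the same direction on 20 of 20 chromosomes. Fragment lengths of the libraries and the settings of the peak calls were not used here.

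The gathering of knockout-only hotspots at gene ends was set against technical accounts. A detection limit of the wild type list was predicted to bring the share at gene ends among strong knockout-only hotspots down to that of shared hotspots. Of the 1821 knockout-only hotspots above the wild type median strength, 68.2% (66.0 to 70.3) were at gene ends. They were chosen by knockout strength, so the test cannot tell whether these sites were used weakly in the wild type, below its calling threshold. It shows that the gathering was not limited to weak knockout-only hotspots. Gene-rich surroundings are argued against, since the share at gene ends exceeded that of points 5 kb to either side by 41.9 percentage points (33.5 to 50.3 over chromosomes). Among 3605 isolated long genes, 1100 had a hotspot at a single end and 5 at both, 0.0587 times (0.0191 to 0.137) the 85.2 expected from independent ends, which is consistent with breaks at transcription starts, as a hypothesis. A difference between these libraries or animals that is not due to Ankrd31, and a bias by base composition, stay open and were not tested.

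Of 3 technical readings of the weaker distal autosome ends, the tables argue against those by starting strength and by competition. Shared hotspots of the last 5 Mb differed from the rest by -0.97 on the log2 scale, and by -0.90 (-1.07 to -0.76) when compared within classes of wild type strength, so their starting strength does not account for it. Competition would need more knockout-only hotspots nearby, but distal shared hotspots had fewer within 500 kb (median 1 against 4), and within classes of that number the difference was -1.08 (-1.25 to -0.91). The estimated background of the same hotspots differed by -0.0945 (-0.28 to 0.09), far less than the strength. It is a scaled estimate, and over what stretch it was made is not given in the sources used here. It thus cannot settle whether coverage of distal DNA was lower in the knockout library. A role of ANKRD31 at distal ends is a candidate explanation, while a different mix of germ cell stages in the knockout testis and a difference between the few animals stay open and untested.

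The strongest knockout hotspot, on chromosome 8 from 47002691 to 47005005 inside Enpp6, singled out after its values were seen, had a strength of 405 in the wild type and 7346 in the knockout (21.9-fold higher), while the other 13 shared hotspots within 2 Mb were all lower (-3.65 to -0.54); the 4 Mb held 26 wild type hotspots, 12 of them wild-type-only, and 14 knockout hotspots, 0 of them knockout-only, with a summed strength of 8332 and 8469, or 7927 and 1123 without this hotspot. Extra copies or misplaced reads at this hotspot alone would leave its neighbours in place, and loss of 1 of 2 copies around it would lower them by no more than 1 log2 unit, but their median was -2.16 (-2.98 to -1.08). Loss of both copies in all knockout cells would leave none of the other 25 wild type hotspots, yet 52% (31.3 to 72.2) were in the knockout list; loss of DNA in part of the animals or cells, or in stretches between these hotspots, cannot be told apart, since the ratio of their background reads, 0.512 (0.291 to 0.903), rests on few reads and its interval includes the 0.761 of all shared autosomal hotspots. Neighbours within 1 Mb of the 20 other strong hotspots that gained over 2-fold had a median of 0.19 (-0.13 to 0.40), so these 20 gains did not go with weaker neighbours, unlike the places with many knockout-only hotspots above. A rearrangement or strain variant carried by the knockout animals, and a local effect of 1 very strong hotspot on its surroundings, may each underlie it, and neither was tested.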
